A study of Caenorhabditis elegans with 11 samples.

How the data were processed

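Total RNA from whole N2 hermaphrodites of C. elegans aged 1, 5, 10 and 20 days was made into small RNA libraries with the TruSeq small RNA kit, per the labels' protocols. Samples were grouped by the age in their labels, with 3, 3, 3 and 2 libraries, and replicate numbers only name the libraries. The deposited values are raw counts of reads per miRNA hairpin name, whole numbers that the authors did not normalize, as column totals from 955506 to 1800586 show. Per the submitters' processing notes, CASAVA 1.8.4, Trimmomatic 0.36, BWA 0.7.12-r1039 and SAMtools 1.3.1-9 were used. The reference sequences, the genome build, the mismatches allowed, the treatment of reads that match several hairpins and the counting rule are not given in the sources used here. Reads shared by near-identical hairpins, such as mir-44 and mir-45 or members of 1 seed family, may therefore have been split, dropped or counted more than once, and values of such members are uncertain. Both arms of a hairpin enter 1 count, so a change can belong to either arm, and the planned test of arm usage was not run.

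Hairpin names were matched to the Ensembl release 115 annotation of WBcel235: 245 of 250 names had 1 place, and coordinates are 1-based. Of the other 5, 3 had no match by name, let-7 among them, and 2 had a name at 2 places, so no coordinates are given for them. Neighbouring hairpins on 1 strand were placed in 1 cluster where the gap between them was at most 10000 bases.

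Counts were analysed in R 4.3.3. Hairpins were kept by edgeR's filterByExpr with its defaults (minimum count 10, minimum total count 15, by age), which left 145 of 250. Library sizes were scaled by TMM, and dispersions and quasi-likelihood F-tests came from edgeR 4.0.16 in 1 fit to all 11 libraries with age as a factor, so that the 20-day group with 2 libraries shared its estimate of spread with the others. Log2 fold changes used edgeR's prior count of 0.125, and SEs were the unshrunk change divided by the square root of its F statistic. The biological coefficient of variation was 12.5%. Tests covered the 4 ages together, 5 comparisons of 2 ages and a slope on log2 age, each with Benjamini-Hochberg adjustment over 145 hairpins and a threshold of 0.05. CPM values given as mean ± SD are TMM-scaled, and log2 CPM for the principal components used a prior count of 2. A floor of 3 counts, the limit that a count of 0 allows, was used for low counts. Reads without molecular identifiers are not independent molecules, so counting limits cover counting error only.

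Before the data were examined, 13 lists were fixed: 11 seed families (let-7, mir-35, mir-51, mir-58, mir-63, mir-44, mir-72, mir-2, mir-50, mir-238 and lin-4), miRNAs known to affect lifespan, and tissue-restricted miRNAs. The mir-35 family also served as the marker of embryos and germline. The 12 lists with at least 3 tested members were tested with camera in limma 3.58.1, with Benjamini-Hochberg adjustment over 60 pairs of list and comparison. Named hairpins followed a rule fixed at the same time: per comparison, the 8 largest rises and 8 largest falls among changed hairpins with a mean of at least 50 CPM, the 5 smallest p-values among the 4 ages, the 5 most abundant hairpins and every tested list member. Shares of counts were compared by exact two-sided permutation of the F statistic.

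The steps were tested on simulated counts for the 145 hairpins, with 20 changed 2-fold and 20 changed 4-fold. For 20 against 1 day, 17 of the 20 smaller and 18 of the 20 larger changes were recovered, and 3 of 105 unchanged hairpins were called. For 5 against 1 day these were 18, 20 and 3, for 10 against 1 day 17, 20 and 1, for 10 against 5 days 16, 20 and 1, and for 20 against 10 days 17, 19 and 0. Simulated rises and falls were equal in number and most hairpins were left unchanged. The simulation therefore does not check the scaling of libraries in which most hairpins change. Alternatives were RLE, upper-quartile and total-count scaling, no filter or a mean of at least 50 CPM, DESeq2 1.42.0, edgeR with robust fitting, limma-voom with lane as a random block, lane as a fixed term, fits to the 2 ages alone, and each library left out in turn. For the trend these also included age in days without a log scale and a fit without the 20-day group, for the shares their log2 and TMM-scaled values, and for the lists an estimated correlation. The number after the letter L at the end of each description was taken as a sequencing lane, which the labels do not state in words. Another alternative, summing hairpin copies, was chosen after the data were seen.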

Results

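Small RNA was sequenced from total RNA of whole N2 hermaphrodites, N2 being the standard laboratory strain of the nematode Caenorhabditis elegans, at 4 ages. The ages of 1, 5 and 10 days had 3 libraries each and the age of 20 days had 2, which made 11 libraries. From which stage the days were counted is not given in the sources used here. The deposited table held read counts for 250 microRNA (miRNA) hairpins, the precursors from which mature miRNAs are cut, with 1 value per hairpin and no split into its arms. Total counts per library were 1414304, 1491708 and 1800586 at 1 day, 1658343, 1233398 and 1660390 at 5 days, 1032059, 1592781 and 1548317 at 10 days, and 1650059 and 955506 at 20 days. Between 172 and 187 hairpins had a count in each library, and 28 had none in any. The 145 hairpins with enough counts to be tested held 99.99% of all counts. At these depths the value of 1 count lay between 0.555 and 1.05 CPM (a count scaled to the usual common library size), before TMM scaling. Without a spike-in named in the labels, every level is an abundance relative to the other miRNAs of its library, and a rise or fall is a change in that relative abundance. Libraries of 1 age differed from each other by more than counting noise in all 10 same-age pairs, so none was treated as a repeat of another. Nothing in the labels says that libraries of 1 age came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

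The first question was which hairpins differed among the 4 ages. mir-82, a member of the bantam-related mir-58 seed family, was the most abundant hairpin, with a mean of 152254 CPM over all libraries, followed by mir-40 of the embryonic mir-35 family (112702 CPM), the glial mir-228 (89449.7 CPM), mir-58a (82049 CPM) and mir-80 (80984 CPM). The smallest p-values belonged to mir-237, a relative of the developmental timing miRNA lin-4 (adjusted p = 2.37e-13), mir-2208a (adjusted p = 3.90e-12), let-7, which times the passage from larva to adult (adjusted p = 4.90e-12), mir-34, a miRNA of the DNA damage and stress responses (adjusted p = 5.88e-11), and mir-4813 (adjusted p = 9.13e-11). In all, 116 of 145 hairpins differed among the ages by edgeR's quasi-likelihood F-test at a Benjamini-Hochberg adjusted p under 0.05. In a principal component analysis of the libraries, the component with 67.7% of the variance placed the ages in their order, and the component with 16.7% set the 5- and 10-day libraries apart from those of 1 and 20 days. Pearson's r of log2 CPM across hairpins, which are not independent replicates, was 0.993 to 0.997 for the 10 library pairs of 1 age and 0.922 to 0.989 for the 45 pairs of different ages, 4 of which shared a lane (0.925 to 0.987).

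**Figure D1:**
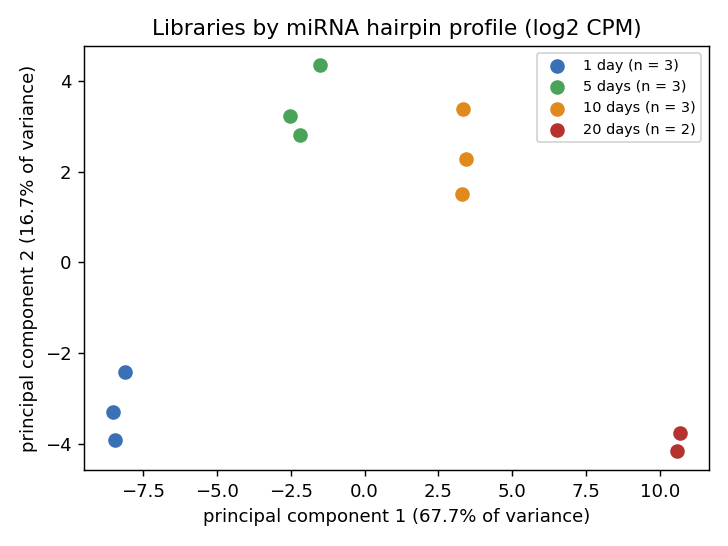
Principal component scores of the 11 libraries from log2 CPM of the 145 tested hairpins, with the first component (67.7% of the variance) on the x axis and the second (16.7%) on the y axis. Each point is 1 library, coloured by age; the ages follow each other along the x axis, and the 5- and 10-day libraries lie above those of 1 and 20 days.

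Between 1 and 5 days, the 3 hairpins of the mir-238 seed family rose, and let-7, mir-241 and mir-237 fell. mir-239a rose 3.71-fold, from 415 ± 43.2 to 1539 ± 346 CPM (SD, n = 3 each; log2 change 1.89 ± 0.19 (SE), adjusted p = 2.61e-07), mir-239b rose 2.27-fold and mir-238 rose by 0.91 on the log2 scale. mir-34 rose 2.22-fold, from 391 ± 34.6 to 871 ± 99.2 CPM (n = 3 each). mir-355 rose 3.43-fold, and mir-75, mir-77 and mir-248 rose by 1.08, 1.01 and 0.89 on the log2 scale. Of the hairpins that fell, let-7 fell 2.76-fold, its seed relative mir-241 2.72-fold and mir-237 2.70-fold. Their families did not move as 1: mir-793 fell by 0.60 on the log2 scale, while mir-48 (0.30) and mir-84 (0.49) of the let-7 family rose, changes that no longer passed with upper-quartile scaling, and lin-4 (-0.20) did not pass. mir-48 also lost its call without replicate 1 of the 1-day group (0.26) or replicate 1 of the 5-day group (0.24), and mir-84 without replicate 3 of the 1-day group (0.45). Among hairpins with a mean of at least 50 CPM, the steepest falls were those of mir-4813, 4.27-fold from 159 ± 7.35 to 37.3 ± 3.68 CPM, and mir-235, 3.20-fold from 19566 ± 2088 to 6121 ± 1198 CPM (n = 3 each). mir-235 is the worm relative of vertebrate miR-92 and holds larval blast cells at rest during starvation. mir-230, mir-74 and mir-59 fell by 1.47, 0.93 and 0.93 on the log2 scale. The 2 ages did not overlap for any of the 16 hairpins with the largest rises or falls among those with at least 50 CPM. edgeR called 69 of 145 hairpins changed, 31 higher and 38 lower at 5 days, 28 of them over 2-fold. Over all 145 tested hairpins, 76 (52.4%) had no overlap between the ages, where chance gives 10%. With upper-quartile scaling, which moved the median log2 change of all hairpins by -0.18, 21 were higher and 46 lower.

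At 10 days the same question was asked against 1 day. mir-237, which lies between genes on chromosome X (8154084 to 8154182, plus strand, WBcel235), fell from 38669.6 ± 733 to 4462 ± 489.6 CPM (SD, n = 3 each), a fall of 8.67-fold (log2 change -3.12 ± 0.14 (SE), adjusted p = 7.43e-12). mir-230 fell 7.27-fold, mir-4813 4.77-fold, mir-235 4.42-fold, let-7 4.21-fold and mir-241 2.74-fold, while mir-59 and mir-74 fell by 0.98 and 0.97 on the log2 scale. Among hairpins with a mean of at least 50 CPM, the largest rise was that of mir-355, 5.36-fold from 57.1 ± 2.53 to 307 ± 5.21 CPM. mir-239a rose 5.16-fold, mir-34 4.90-fold and mir-239b 4.53-fold. mir-786, an intestinal miRNA needed for the defecation rhythm, rose by 1.55 on the log2 scale, mir-1018 by 1.52, mir-53 by 1.32 and mir-84, of the let-7 family, by 1.27. Of the mir-35 family, whose 8 members are made in oocytes and embryos and are needed for embryonic survival, 7 rose (8 when adjusted over the list alone), among them mir-35 by 1.05 and mir-38 by 1.21, and mir-41 had a log2 change of 0.45 ± 0.21 (SE) that did not pass. The call of mir-40 was lost with RLE or total-count scaling, without a filter or with a minimum of 50 CPM, with DESeq2, with copies summed and in the fit to the 2 ages alone, which left 6 of the 8. It was also lost without replicate 1 or 2 of the 1-day group, replicate 1 or 3 of the 10-day group or either 20-day library (log2 changes of 0.16 to 0.34). With upper-quartile scaling or lane in the model, as a fixed term or a random block, all 8 rose. edgeR called 93 of 145 hairpins changed, 54 higher and 39 lower at 10 days, 46 of them over 2-fold. The median log2 change of all tested hairpins was 0.15 with TMM and 0.02 with RLE factors. With total counts alone, which moved the median log2 change by -0.28, 40 were higher and 51 lower, while RLE size factors, which moved it by -0.13, left 47 higher and 43 lower.

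The widest span of ages was 20 days against 1 day. mir-237 fell 27.4-fold to 1414 ± 185 CPM (SD, n = 2), with a log2 change of -4.77 ± 0.19 (SE) and an adjusted p of 4.38e-13. let-7 fell 14.0-fold, from 3786 ± 411 (n = 3) to 271 ± 16.5 CPM (n = 2; adjusted p = 2.56e-12), and mir-241 8.85-fold (adjusted p = 1.36e-10). mir-70, in an intron of the peroxisomal transporter gene pmp-5 (V, 6665536 to 6665635, minus strand, WBcel235), fell 4.48-fold from 27637 ± 1948 (n = 3) to 6176 ± 423 CPM (n = 2). mir-235, mir-4813, mir-230 and mir-59 fell by 2.03, 1.99, 1.81 and 1.79 on the log2 scale. mir-239b rose 22.8-fold, from 288 ± 22.0 (n = 3) to 6564 ± 2369.6 CPM (n = 2; log2 change 4.51 ± 0.27 (SE), adjusted p = 1.36e-10). Its neighbour mir-239a rose 6.47-fold; the 2 hairpins lie on opposite strands of chromosome X, at 11791302 to 11791399 (minus) and 11792445 to 11792542 (plus). mir-34 (X, 2969752 to 2969848, minus strand, between genes) rose 8.53-fold from 391 ± 34.6 to 3339 ± 507 CPM, with an adjusted p of 1.31e-11. mir-1018 rose 10.6-fold, mir-240 5.04-fold, mir-355 4.43-fold, and mir-2209a and mir-786 by 2.07 and 1.99 on the log2 scale. The low-abundance mir-2208a, named for its small p-value among the 4 ages, rose from 4.97 ± 1.57 to 157 ± 7.57 CPM. edgeR called 91 of 145 hairpins changed, 48 higher and 43 lower at 20 days, and 63 changed over 2-fold, 34 up and 29 down. Over all 145 tested hairpins, the ages did not overlap for 110 (75.9%), where chance gives 20%. Total counts, which moved the median log2 change by -0.20, gave 44 higher and 56 lower, and upper quartiles, which moved it by -0.11, gave 45 and 48. All 16 hairpins with the largest changes at 50 CPM or more kept their calls under every alternative tried and with any 1 library left out.

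**Figure D2:**
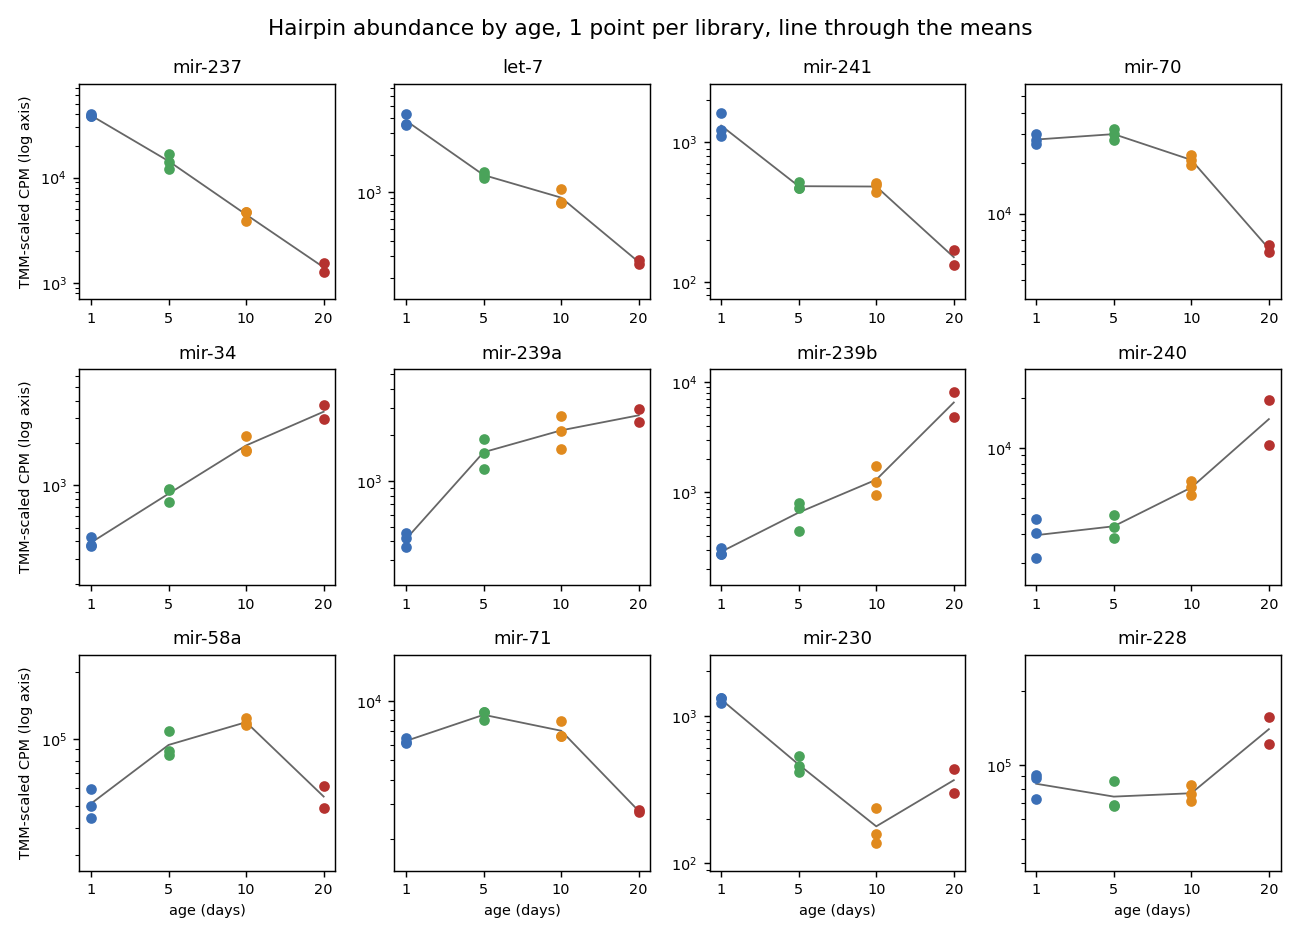
TMM-scaled CPM on a log axis against age in days (evenly spaced) for 12 hairpins, with 1 point per library (n = 3 at 1, 5 and 10 days, n = 2 at 20 days) and a line through the mean of each age. By their means, mir-237, let-7 and mir-241 were lowest at 20 days, and mir-34, mir-239a, mir-239b and mir-240 were highest there. The 10- and 20-day libraries overlapped for mir-239a. mir-58a was highest at 10 days and mir-230 was lowest at 10 days.

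The seed families and functional lists were followed from 1 to 20 days, and counts adjusted over the list alone were the same unless given. All 8 tested members of the mir-35 family rose, with a median log2 change of 1.51. Of these, mir-35 to mir-41 form a cluster on chromosome II (11537608 to 11538404, plus strand, in an intron of Y62F5A.9 on the other strand), and mir-42 lies farther along (11889811 to 11889905, between genes). mir-36 rose by 1.84, mir-42 by 1.67 and mir-40 by 0.36; with upper-quartile or total-count scaling or a minimum of 50 CPM mir-40 and mir-41 no longer passed and 6 rose, and mir-41 did not pass with lane as a random block either (0.51, adjusted p = 0.0601). mir-40 also lost its call without replicate 1 of the 1-day group (0.29) or replicate 3 of the 5-day group (0.36), and mir-41 without replicate 1 (0.55) or 3 (0.50) of the 1-day group, replicate 1 of the 5-day group (0.55) or replicate 2 of the 20-day group (0.18). The 3 members of the mir-238 family, mir-238, mir-239a and mir-239b, all rose, with a median of 2.69. The 3 tested members of the mir-44 family, mir-44, mir-45 and mir-61, also rose, but mir-44 and mir-45 had nearly the same count in every library (ratios of 0.990 to 1.03), so reads of 1 may have been counted for both and each value is uncertain. Both members of the lin-4 family fell, lin-4 itself by 0.82 on the log2 scale. The let-7 family parted: let-7 and mir-241 fell, mir-84 rose by 1.40 and mir-795 by 0.58, and mir-48, mir-793 and mir-794 had log2 changes of -0.13, -0.19 and 0.08 that did not pass. In the mir-63 family 4 of 5 fell, among them mir-63 by 1.03 and mir-229 by 0.97, and mir-66 did not pass. The mir-51 family had 3 rises (mir-52, mir-53, mir-54) and 2 falls (mir-51, mir-55) among 6, and mir-55 no longer passed without replicate 1 of the 20-day group (-0.42). The mir-58 family had 1 rise (mir-2209a) and 2 falls (mir-80, mir-81) among 6, the mir-72 family 2 rises (mir-72, mir-73) and 1 fall (mir-74) among 3, and the mir-2 family 2 rises (mir-2, mir-43) among 4, of which mir-2 no longer passed with upper-quartile or total-count scaling or a minimum of 50 CPM. The mir-50 family had 1 rise (mir-62) and 1 fall (mir-50) among 3, or 2 rises and 1 fall when adjusted over the list alone. The fall of mir-50 was lost with lane as a fixed term (-0.44) and without replicate 2 of the 1-day group (-0.35) or replicate 1 (-0.31) or 2 (-0.38) of the 20-day group. With total-count scaling 4 members of the let-7 family rather than 2 and 3 of the mir-58 family rather than 2 passed as lower, and with RLE factors 2 of the mir-50 family passed as higher.

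Of the 11 tested hairpins on the list of miRNAs reported to affect lifespan, 6 rose from 1 to 20 days (mir-34, mir-238, mir-239a, mir-239b, mir-246 and mir-228) and 4 fell (let-7, lin-4, mir-71 and mir-80). mir-246 rose from 7134 ± 301 (n = 3) to 18848 ± 392 CPM (n = 2) and mir-71, whose loss shortens life, fell 2.26-fold from 6271 ± 209 to 2777 ± 56.5 CPM. mir-83 had a log2 change of 0.32 ± 0.24 (SE) and did not pass. Among 8 tissue-restricted hairpins, the muscle mir-1 fell 3.21-fold from 509.7 ± 64.3 to 158 ± 24.8 CPM, the intestinal mir-60 fell 2.46-fold and lsy-6, of the taste neurons, fell by 1.39 on the log2 scale. Without replicate 1 of the 20-day group the change of lsy-6 was -0.99 and no longer passed (adjusted p = 0.107). The glial mir-228 rose by 0.74, and mir-240 and mir-786, neighbours on chromosome X (7882622 to 7882840, plus strand), rose too, while the neuronal mir-124 (-0.53) and mir-791 (-0.21) did not pass. With total-count scaling 4 of this list rather than 3 passed as lower. With TMM the list's median (-0.37) and mean (-0.0056) were negative while its list test (camera) pointed up (adjusted p = 0.999). A competitive test of each list against the other hairpins (camera, correlation preset to 0.01) over 60 pairs of a list and a comparison called 4. These were the mir-35 family at 20 against 1 day (adjusted p = 0.0296) and at 10 against 5 days (adjusted p = 0.0123), and the mir-238 family at 5 against 1 day (adjusted p = 0.0296) and at 20 against 1 day (adjusted p = 0.0367). None held with a correlation estimated from the data: the adjusted p was then 0.639, 0.529, 0.529 and 0.529 in that order.

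**Figure D3:**
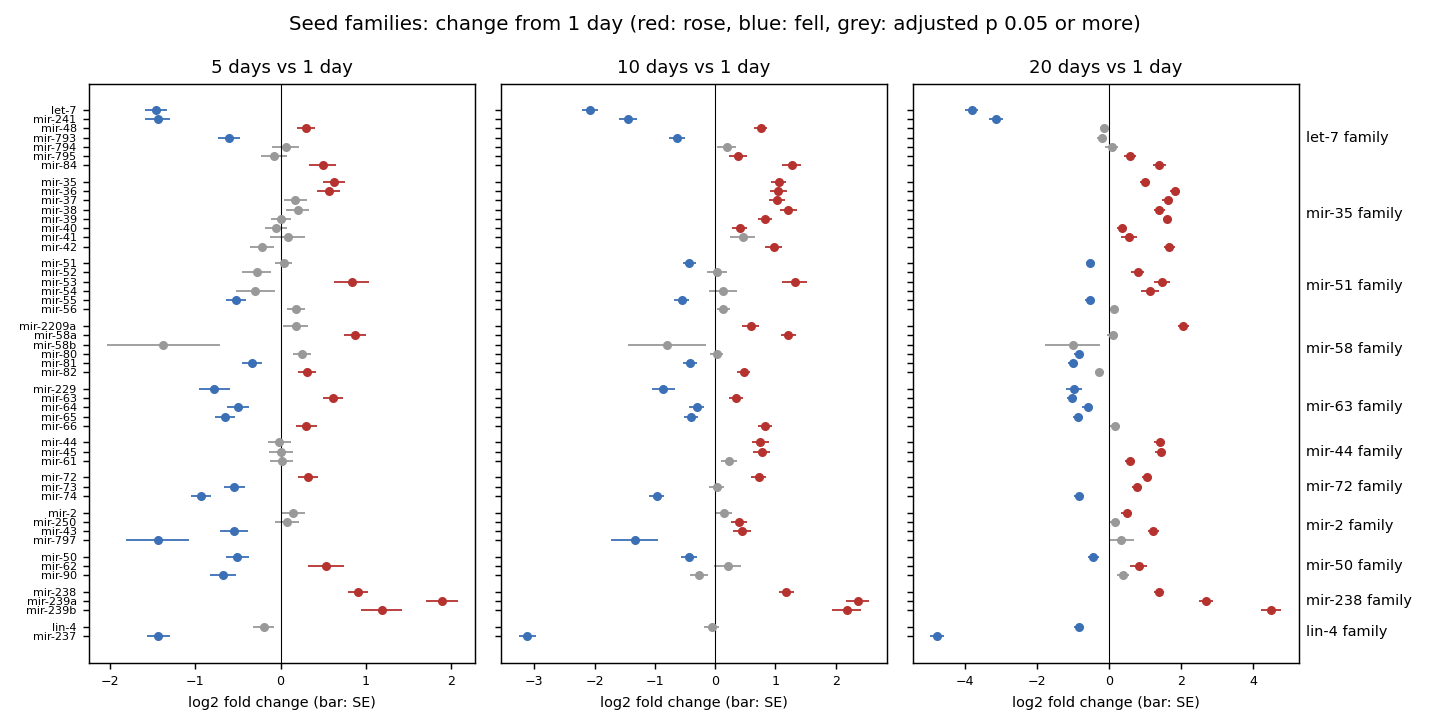
Log2 fold change from 1 day to 5, 10 and 20 days (x axes, each with its own range) of every tested member of 11 seed families (y axis), with points for edgeR estimates, bars for their SE, red for a rise and blue for a fall at an adjusted p under 0.05, and grey for the rest. All 8 members of the mir-35 family were higher at 20 days, although mir-40 and mir-41 did not pass with upper-quartile or total-count scaling and under some other alternatives, while members of the let-7 and mir-51 families lay on both sides of 0.

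With TMM scaling, the step from 5 to 10 days had the fewest changed hairpins of the 5 comparisons. This order followed the scaling: upper quartiles gave 74, against 67 for 5 against 1 day and 70 for 20 against 10 days. mir-237 fell 3.21-fold again (log2 change -1.68 ± 0.14 (SE), adjusted p = 7.15e-08), mir-230 fell 2.62-fold and mir-60 fell by 0.68 on the log2 scale. mir-1018 rose 3.59-fold, from 16.0 ± 5.51 to 58.5 ± 13.8 CPM, mir-34 2.20-fold, and mir-42, mir-43, mir-231, mir-38, mir-239b and mir-786 by 1.19, 0.99, 1.01, 1.01, 0.99 and 0.98 on the log2 scale. In the mir-35 family 7 of 8 passed as higher, also when adjusted over the list alone, with a median over all 8 of 0.65, but mir-35, mir-36 and mir-40 often lost their calls. With RLE or total-count scaling, without a filter or with a minimum of 50 CPM, with DESeq2 or with copies summed, 4 of the 8 rose, as they did without replicate 2 of the 1-day group or either 20-day library. Without replicate 2 of the 5-day group or replicate 1 of the 10-day group, or in the fit to the 2 ages alone, 5 rose, and without replicate 3 of the 5-day group 6 did. With lane as a fixed term mir-36 did not pass (0.37, adjusted p = 0.0906). let-7, mir-70, mir-235 and mir-51 fell by 0.61, 0.51, 0.47 and 0.46; the call was lost for let-7 with lane as a fixed term (adjusted p = 0.221) and for the other 3 with upper-quartile scaling (adjusted p of 0.104, 0.260 and 0.188), and for mir-235 also without replicate 3 of the 5-day group, where the log2 change stayed at -0.47 (adjusted p = 0.0527). The median log2 change of all tested hairpins was 0.19 with TMM and 0.41 with upper quartiles. With RLE factors and total counts it was -0.01 and -0.02, so TMM values for this step lie above those of RLE or total counts. edgeR called 54 of 145 hairpins changed, 42 higher and 12 lower at 10 days, 13 over 2-fold, but that split followed the scaling. It was 26 to 28 with RLE factors, 25 to 29 with total counts and 65 to 9 with upper quartiles, as the median log2 change moved by -0.20, -0.20 and 0.22, and 22 to 26 hairpins were higher and 21 to 24 lower when replicate 2 of the 1-day group, replicate 1 of the 10-day group or either 20-day library was left out.

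From 10 to 20 days, mir-70, the muscle mir-1, the intestinal mir-60 and the timing miRNA let-7 were among the hairpins that fell. mir-70 fell 3.38-fold (adjusted p = 1.84e-08), mir-1 2.83-fold from 451 ± 82.9 (n = 3) to 158 ± 24.8 CPM (n = 2), mir-71 2.54-fold, mir-63 2.59-fold and mir-60 2.52-fold. let-7, mir-241 and mir-237 fell 3.33-fold, 3.23-fold and 3.16-fold. mir-239b rose 5.03-fold, mir-1018 3.68-fold, mir-240 2.59-fold and mir-230, lower at 10 than at 1 day, 2.07-fold. mir-2209a, mir-246 and mir-228 rose by 1.48, 0.94 and 0.87 on the log2 scale. The rise of mir-54, 1.00, was 0.36 and no longer passed with lane as a fixed term (adjusted p = 0.0617), and that of mir-240 was then 0.73. Replicates 1 and 2 of the 20-day group differed widely for mir-239b (4888 and 8239 CPM), mir-240 (10356 and 19485 CPM) and mir-54 (8036 and 16172 CPM). Without replicate 1 the log2 changes of these 3 were 2.93, 2.06 and 1.72. Those larger values rest on replicate 2 alone, the higher library in each case, and which of the 2 is typical of the age cannot be told. For mir-54, replicate 1 (8036 CPM) lay close to replicate 1 of the 10-day group (7929 CPM), so the size of its rise rests largely on replicate 2. edgeR called 65 of 145 hairpins changed, 29 higher and 36 lower at 20 days, 27 of them over 2-fold. The median log2 change of all tested hairpins was -0.09 with TMM. RLE scaling, which moved the median by 0.15, gave 42 higher and 30 lower, upper-quartile scaling, which moved it by -0.18, gave 23 and 47, and total counts gave 36 and 35. Higher hairpins also outnumbered lower ones without replicate 1 (36 and 34) or 2 (51 and 29) of the 1-day group, replicate 1 of the 10-day group (50 and 28), or replicate 1 (42 and 26) or 2 (39 and 25) of the 20-day group. Over all 145 tested hairpins, 98 (67.6%) had no overlap between the ages, where chance gives 20%.

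Read across the ages, 17 hairpins were higher at 10 days than at 1 day and higher again at 20 days, among them mir-34, mir-239b, mir-240, mir-36 and mir-42. Another 13 fell in both steps, among them mir-237, let-7, mir-241 and mir-59. A rise to 10 days followed by a fall to 20 days was seen for 11 hairpins, which included 2 of the mir-58 family, mir-58a and mir-82. The rise of mir-82 lost its call with total counts (log2 change 0.19) or a minimum of 50 CPM (0.14). That of mir-63, also among the 11, lost its call under these and other alternatives. mir-58a went from 51218 ± 7825 CPM at 1 day to 118925 ± 4969.8 at 10 days and 55096 ± 8855 at 20 days, and mir-77 from 4382 ± 449 to 10249 ± 965 and 4535 ± 373 (SD, n = 3, 3 and 2). The opposite path was taken by 3 hairpins, mir-230, mir-793 and mir-797, although the rise of mir-793 and both steps of mir-797 lost their calls under at least 1 alternative. With the other scalings these 4 counts were 14 to 20, 12 to 17, 8 to 16 and 2 to 9. In a test of a linear trend on log2 age, 70 of 145 hairpins passed, 38 upward and 32 downward. Per doubling of age, mir-34 gained 0.71 on the log2 scale (adjusted p = 3.89e-07), while let-7 and mir-237 had slopes of -0.76 and -1.03 (adjusted p = 1.80e-06 and 2.04e-06). With lane as a fixed term in the trend 34 hairpins passed, 17 in each direction, and with total counts 32 rose and 46 fell.

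The sum of the mir-35 family took 18.8% ± 2.22 of all counts at 1 day, 20.3% ± 1.12 at 5 days, 25.2% ± 0.894 at 10 days (SD, n = 3 each) and 29.0% ± 1.69 at 20 days (n = 2). The share of the let-7 family was 2.31% ± 0.0721, 2.24% ± 0.0515, 2.67% ± 0.0845 and 1.87% ± 0.270 in the same order, and that of mir-82 alone 14.7% ± 0.925, 17.1% ± 0.932, 16.7% ± 0.419 and 10.6% ± 0.623. In exact permutation tests of the F statistic over the 92400 arrangements of the ages, p was 3.90e-04, 1.95e-04 and 3.90e-04, and 3.90e-04 for each after adjustment for the 3 tests. The lanes that the labels appear to name were shared by libraries of 2 ages in 4 cases, which allowed a comparison within a lane. All 91 hairpins called at 20 against 1 day had the same sign in the pair of lane 1, as had all 69 at 5 against 1 day in lane 3, all 54 at 10 against 5 days in lane 5 and all 65 at 20 against 10 days in lane 7. Each of these pairs is 1 library against 1, and those libraries also entered the tests. In the same order, 90, 67, 50 and 65 of the called hairpins had no overlap between the ages. For those hairpins any pair of libraries from the 2 ages gives the called sign. The agreement within lanes was thus nearly fixed in advance and says nothing about an effect of lane.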

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

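No test here was chosen after the results were seen, since the fit without a count filter was planned. The 105 hairpins too low to be tested include the 28 without a count in any library. Without a count filter, edgeR called 4 hairpins below the usual filter as different among the ages that reached more than 3 counts, the limit that a count of 0 allows, in at least 1 library. mir-2221 (X, 1390847 to 1390964) reached 9 counts in 1 library, and its summed counts were 0 at 1 day, 18 at 5 days, 18 at 10 days and 2 at 20 days (adjusted p = 5.65e-05). mir-4929 (II, 13461755 to 13461864, in an intron of E01G4.3) reached 12 counts, with sums of 6, 14, 22 and 8 (adjusted p = 0.0408). mir-796 reached 8 counts, with sums of 7, 10, 1 and 9 (adjusted p = 0.0451), and mir-4805 reached 5 counts, with sums of 2, 5, 2 and 9 (adjusted p = 0.0444). The age of 20 days has 1 library fewer in these sums, and 8 of the 9 counts of mir-796 at that age came from replicate 1. Apart from mir-2221, these calls lie just under the threshold of 0.05. No explanation was tested for these values.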

How the results depend on the processing

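All alternatives were planned except the summing of hairpin copies, chosen after the data were seen. Every count of changed hairpins stayed within 1.5 times its value except 1: the trend fell from 70 to 34 hairpins with lane as a fixed term, and the cause was not tested. A term for each lane leaves little of the 11 libraries to measure the spread, which by itself weakens such a fit. Leaving out each library in turn gave 110 to 118 hairpins for the 4 ages, 61 to 73 for 5 against 1 day, 84 to 93 for 10 against 1 day, 86 to 98 for 20 against 1 day, 41 to 60 for 10 against 5 days, 59 to 80 for 20 against 10 days and 62 to 76 for the trend. Without 1 of the 20-day libraries the lone remaining one was assumed to vary like the other ages. The gene list calls went from 4 to 0 with an estimated correlation and ranged from 1 to 5 over the left-out libraries: 1 without replicate 1 or 2 of the 1-day group or replicate 1 of the 10-day group, and 2 without replicate 3 of the 1-day group or replicate 2 of the 5-day group. All 3 shares kept their direction and passed under every alternative tried for them.

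For single named hairpins, 8097 alternative values over 370 pairs of hairpin and comparison were computed: 7432 kept direction and side of the threshold, 363 lost the call, 295 gained it and 7 reversed. The reversed values all belonged to changes that had not passed. With lane as a fixed term these were mir-45 at 5 against 1 day (-0.33) and mir-228 at 10 against 1 day (0.31). At 10 against 1 day, mir-73 was -0.26 with total counts and -0.30 with a minimum of 50 CPM, and mir-80 was -0.26 and -0.31. mir-50 at 20 against 10 days was 0.38 without replicate 1 of the 10-day group, in a range from -0.13 to 0.38 over the left-out libraries. The causes were not tested. No paired analysis was possible because the labels give no replicate numbers shared between ages. Arm usage was not run, since the table has 1 value per hairpin. Depth limits hairpins near the floor: mir-799 had 1 count at 20 days, mir-1020 had 2 and mir-788 had 3, so no fold is given for them.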

Other observations

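The tests of the mir-35 family and of the genomic clusters were chosen after the results were seen; the counts over other splits of the libraries were planned before. Outside the rule for named hairpins, 33 hairpins changed from 1 to 20 days, 13 higher and 20 lower, and 22 of them had a mean under 50 CPM. Of these, mir-4807, mir-2220, mir-2208b, mir-1022, both copies of mir-789, mir-1830, mir-357 and mir-358 were chosen after their values were seen, while their neighbours mir-1018, mir-2208a and mir-2209a are named by the rule. Near the left end of chromosome X, 11 annotated hairpins on the plus strand lie between 1872466 and 1880038, and the 3 that could be tested all rose. Of these, mir-4807 and mir-2220 passed the count filter only through the 20-day libraries. Their rise was therefore nearly fixed in advance and is no support for a change of the whole cluster. mir-4807 had 2, 5, 9 and 56 summed counts at 1, 5, 10 and 20 days, the last from 2 libraries rather than 3, mir-2220 had 4, 1, 10 and 27, and mir-1018 rose 10.6-fold. On chromosome IV (1021772 to 1027281, plus strand), mir-2208a, mir-2208b and mir-2209a also rose from 1 to 20 days, by 4.94, 3.40 and 2.07 on the log2 scale. Here mir-2208b passed the filter only through the 20-day libraries. mir-1022 rose from 88.2 ± 3.63 (SD, n = 3) to 253 ± 34.4 CPM (n = 2).

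Falling hairpins outside the rule included both copies of mir-789, from 95.9 ± 11.8 to 6.23 ± 1.13 CPM for mir-789-1 and from 68.1 ± 4.58 to 9.74 ± 6.11 CPM for mir-789-2 (SD, n = 3 and 2), whose reads cannot be assigned with certainty between them. mir-1830 fell by 3.45 on the log2 scale. mir-357 and mir-358, neighbours in an intron of symk-1 on its opposite strand (V, 8580542 to 8580967), fell by 2.67 and 2.24.

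The rise of the mir-35 family to 20 days stands out because its members are known from oocytes and embryos. With upper-quartile or total-count scaling, a minimum of 50 CPM or without replicate 1 of the 1-day group, mir-40 and mir-41 did not pass and 6 members rose. The family's list test at 20 against 1 day (camera) did not pass with an estimated correlation (adjusted p = 0.639). Scaling as the whole cause is argued against, since the lowest median change over 4 scalings was still 1.31. Moving reads between members is argued against as the whole cause too. The family's summed share of counts rose by 0.62 on the log2 scale, against a median over members of 1.31 by total counts. Its 1-day and 20-day libraries did not overlap, where chance gives 20%. How much shared reads added to the rises of single members stays open, and reads counted more than once would also enter the sum. Room left by some abundant hairpins that fell would lift every other hairpin by 1 factor, and the tables argue against it as the whole cause. By total counts, the 137 tested hairpins outside the family had a median change of -0.29 (95% bootstrap interval -0.49 to -0.07), and the 42 of them with at least 1000 CPM one of -0.18, against 1.31 for the family. The interval is for a median over hairpins, which are not independent replicates, and does not measure the spread between libraries. A fall of most miRNAs in absolute amount stays open, since no spike-in is named. A larger share of germline or embryo RNA in older whole animals is a candidate explanation that the table could not test, and regulation of the family with age is another.

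Neighbouring hairpins of 1 cluster resembled each other and yet often parted. The tested hairpins in clusters include mir-4807, mir-2220 and mir-2208b, which passed the filter only through the 20-day libraries and so were likely to rise together. Over 18 clusters with 49 tested hairpins, the mean absolute difference in log2 change from 1 to 20 days within clusters was 0.922, against 1.89 when hairpins were reassigned among clusters (permutation p = 0.0001, one-sided, the smallest that 10000 reassignments can give). Shared transcription is a candidate explanation, although clustered members of 1 seed family may also share reads, and neither was tested. The cluster of mir-35 to mir-41, with 7 hairpins of 1 seed family, gave more of the pairs than any other cluster. No mean or p is given without that cluster, or without the hairpins that passed the filter only through the 20-day libraries. Of 55 pairs within clusters, 33 (60%) differed at an adjusted p under 0.05, which argues against counting noise. With lane as a fixed term all 33 (100%) kept their sign and at least 0.5 of their size. That fit draws only on the lanes shared between ages, with 1 library per age in each, and those libraries also gave the differences. It therefore cannot settle whether lane played a part. Pairs overlap in their members, and their errors were treated as independent. The widest gap was between mir-48 and mir-241, -0.13 against -3.15 on chromosome V (14364412 to 14366283), and opposite calls were made for mir-2 and mir-71, mir-80 and mir-238, mir-51 and mir-53, mir-73 and mir-74, and mir-54 and mir-55. Separate promoters, or maturation or decay that differs between members, are candidate explanations left untested.

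Other splits of the libraries gave fewer changed hairpins than the real ages. For the 4 ages, 1 of 100 groupings, the real one, reached 116 hairpins, and the highest of the others had 54. For the trend, 1 of 100 reached 70 and the highest other had 18. Both results argue against chance assignment of single libraries but do not exclude it, since 100 groupings cannot give a share under 1 in 100. They also cannot tell age from culture if the libraries of 1 age shared a culture. For 5 against 1 day, 10 against 1 day and 10 against 5 days the 10 possible splits are too few for a share under 0.05; the real counts were 69, 93 and 54 and the highest other was 0 in each.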
